A study of Homo sapiens with 6 samples.

How the data were processed

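RNA was extracted from NB4 cells in logarithmic growth, 3 libraries of CD69-overexpressing cells and 3 of vector control cells, and poly(A) RNA was made into strand-specific libraries read in pairs on an Illumina NovaSeq, per the labels' protocols. The series' design text calls the libraries biological replicates, and nothing in the sources used here says that they came from separate transductions, so p-values measure the spread between these libraries only. Each group may stand for 1 transduced population. The authors deposited 1 table of counts per gene and library. Per the submitters' processing notes the tools were FastQC, fastp, STAR and featureCounts of the Subread package with the GRCh38 (hg38) build. Their versions, the annotation release, the strand setting and the counting unit were not given in the sources used here. The deposited values were treated as estimated counts. They were whole numbers, so rounding changed nothing, but in control replicate 1, 1496 genes held exactly 4 counts, 777 held 3 and 1084 held 2, and all libraries showed the same excess at 4 and 8. A single fragment may thus stand for about 4 counts, and the true depth may be lower than the totals by that factor. An alternative with counts divided by 4, chosen after seeing the data, was run for this reason.

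The table held 61806 genes, 61757 of them with an entry in the gene name table. Total counts per library lay between 51543550 and 57463020. Positions were taken from a GENCODE annotation of GRCh38 by Ensembl identifier and were found for 97.2% of the tested genes. Part of the counts is uncertain for named genes that share exons with another gene on their strand, which were ITGAD, APOC4-APOC2, HSH2D, GPR141, RAPGEF6, CIITA, CYP51A1, CTSD, HLA-C, MT-CO3 and MT-ATP6. The same holds for named genes with exons over those of a gene on the opposite strand, since the strand setting of the counting was not given. These were SLAMF8, HSBP1L1, CLEC2B, SPHK1, SPNS2, MYBBP1A, ASAH1, ICAM3, BCL2L1, NPC1, CDC25C, CLSPN, BLNK, NCAM1, NFE2, FLI1, and again CIITA and CTSD. No 2 libraries agreed within sampling noise: chi-square per degree of freedom of counts divided by 4 was 2.29 to 14.0 within groups.

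Genes were kept by edgeR's filterByExpr (19485 genes), scaled by TMM and tested with the quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are CPM with TMM factors. A total of 33 gene lists and the chromosomes 1 to 22 and X were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Lists needed at least 5 tested genes and chromosomes at least 20. Adjusted p-values of lists are over the 33 lists. Chromosome medians are over coding genes of at least 5 CPM, and windows of 5 Mb needed at least 8 such genes. The gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule named CD69, the 10 largest rises and falls among changed genes of at least 5 mean CPM whose groups did not overlap, up to 3 members of each list with the smallest p, and the 3 most abundant changed genes in each direction. Other genes are named as chosen after their values were seen or as members of the B lineage pattern, which was also found in the data. The values of 1 gene that the rule named are not reported here.

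The alternatives were RLE, upper-quartile and no scaling factors, no filter, a filter of 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, glmTreat against a fold of 1.2, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were counts divided by 4, overexpressing replicate 1 alone against the controls, and genes of chromosomes 6, 15, 20 and X left out. The test was checked on simulated counts for 19485 genes. It called 14% of genes simulated with a log2 change of 0.5, 50% at 1, 77.6% at 2 and 89.6% at 3, and 14 of 18049 unchanged genes. Figures were drawn with matplotlib 3.10.9. Read-level data were not used here.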

Results

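Gene expression was measured by poly(A) RNA sequencing in NB4 cells, an established line of acute promyelocytic leukaemia, a leukaemia of granulocyte precursors. Of the 6 libraries, 3 came from cells transduced with a lentivirus to overexpress CD69 and 3 from cells carrying the vector control. CD69 is a C-type lectin of the leukocyte surface that appears early after activation. No drug was applied. Total counts were 55716218, 56221245 and 57463020 in the controls and 55280365, 56239830 and 51543550 in the overexpressing libraries. Each library correlated best with the libraries of its own group (Pearson's r across genes, which are not independent replicates, of 0.966 to 0.981 within and 0.942 to 0.958 between groups). Overexpressing replicate 1 stood apart from its group, with a first principal component score of 32.4 against 74.8 and 74.3 for replicates 2 and 3 and -61.7 to -59.5 for the controls.

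CD69 itself (ENSG00000110848; GRCh38 chromosome 12, 9752486 to 9760901, minus strand) was only slightly higher in the overexpressing cells. Its level was 77.6 ± 6.14 CPM (normalised read count relative to library size; SD, n = 3) in the controls and 97.7 ± 1.75 CPM (SD, n = 3) in the overexpressing libraries, a log2 fold change of 0.33 (SE 0.07; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0153), with all 3 overexpressing libraries above all 3 controls. Of the genes that rose, 2546 (92.0%) rose more than CD69. Counts per gene do not separate transcripts of the introduced sequence from those of the cells' own gene. The call was lost when overexpressing replicate 2 was left out (adjusted p = 0.0618, range over all alternatives 0.00239 to 0.260) and when tested against a fold of 1.2 (adjusted p = 0.260), and with overexpressing replicate 1 alone, an alternative chosen after seeing the data (adjusted p = 0.213). Among the 9 tested coding genes that start within 250 kb, looked at after their values were seen, 5 rose and 1 fell. CLEC2B, another C-type lectin, rose from 176 ± 11.3 to 680 ± 43.7 CPM (log2 fold change 1.95, SE 0.08), and KLRF1 fell by 0.84 on the log2 scale (SE 0.21).

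**Figure D1:**
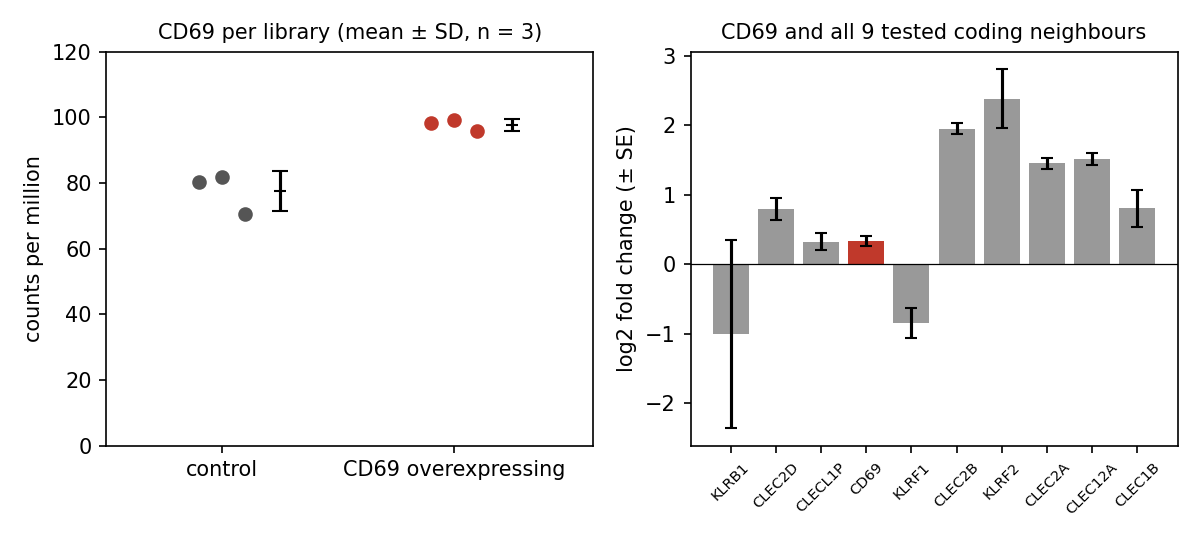
Left, CD69 in CPM for each library, with the mean and SD of each group of 3 beside the points. Right, log2 fold change with its SE for CD69 and all 9 tested coding genes that start within 250 kb, in chromosome order, where CD69 lies at 0.33 and CLEC2B at 1.95.

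The design asks which transcripts differ between CD69-overexpressing and control cells. Among the most raised transcripts were WFDC1, which encodes a secreted WAP-domain protein, CAMKV, a kinase-like vesicle protein, the homeobox gene VENTX, and GAL, the precursor of the neuropeptide galanin. WFDC1 (chromosome 16, 84294646 to 84329851) held 1, 2 and 5 counts in the controls and 1002, 953 and 968 in the overexpressing libraries, a log2 fold change of 8.50 (SE 0.33). CAMKV rose by 8.27 (SE 0.46), VENTX by 7.58 (SE 0.59) and GAL by 7.16 (SE 0.61) on the log2 scale, each from fewer than 1 CPM in every control, so that the size of these folds rests on very few control counts. SLC26A9, an anion transporter, rose from 1.48 ± 0.125 to 162 ± 11.1 CPM (SD, n = 3), and BEX1 from 0.907 ± 0.134 to 100.1 ± 18.0 CPM. The integrin subunit ITGAD (6.98, SE 0.21), the receptor SLAMF8 (6.91, SE 0.58) and the transcription factor EBF3 (6.61, SE 0.29) completed this group with APOC4-APOC2. The last is a read-through transcript that shares exons with APOC2 and held 170, 232 and 1378 counts in the overexpressing libraries, so its value is uncertain. ITGAD shares exons with another annotated gene, and SLAMF8 overlaps one on the opposite strand, which leaves part of their counts uncertain.

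The falls were smaller than the rises. FLT1, a receptor for vascular endothelial growth factor (chromosome 13, 28300344 to 28495145), fell from 10.4 ± 1.27 to 1.84 ± 0.0602 CPM (SD, n = 3; log2 fold change -2.50, SE 0.16), and HPD, an enzyme of tyrosine breakdown, from 29.7 ± 4.21 to 5.76 ± 0.544 CPM. HSH2D, an SH2-domain adaptor, fell from 115 ± 7.96 to 27.2 ± 0.267 CPM and shares exons with RAB8A. The others were the long non-coding RNA PELATON (-2.18), CACHD1 (-2.12), the keratin pseudogene KRT17P6 (-2.09, uncertain because of near-identical copies), GPR141 (-2.09, sharing exons with EPDR1), HSBP1L1 (-2.04, overlapping TXNL4A on the opposite strand), RAPGEF6 (-2.02, sharing exons with another gene) and GPR85 (10.2 ± 0.636 to 2.56 ± 0.562 CPM). Of the most abundant transcripts, the mitochondrial MT-CO3, MT-RNR2 and MT-ATP6 rose by 0.52, 0.50 and 0.30, of which MT-CO3 and MT-ATP6 overlap. The elongation factor EEF1A1 and the glycolytic enzymes GAPDH and ENO1 fell by 0.67, 0.34 and 0.49, all on the log2 scale. The GAPDH call was lost without control replicate 1, 2 or 3 (quasi-likelihood adjusted p = 0.0587, 0.0697 and 0.0528) and without overexpressing replicate 1 or 2. That of MT-ATP6 was lost without control replicate 1 or 2 and without overexpressing replicate 2.

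Over all 19485 genes tested, 2767 were higher and 1937 lower in the overexpressing cells (edgeR quasi-likelihood test, adjusted p under 0.05), together 24.1%. At least 2-fold changes numbered 1046 higher and 376 lower. Against a fold of 1.2 the counts were 1723 and 874, and without overexpressing replicate 2 they were 1783 and 1137. Leaving out control replicate 1 or control replicate 2 gave 1227 and 1287 lower genes, and leaving out overexpressing replicate 1 raised the lower genes of at least 2-fold to 805. With overexpressing replicate 1 alone against the controls, an alternative chosen after seeing the data, 797 genes were higher and 380 lower.

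Of 25 measured genes of cholesterol synthesis, 13 rose, 1 fell and 11 did not pass the test (15 and 1 adjusted over the list alone), with a median log2 fold change of 0.47. INSIG1, a sterol-regulated brake on the pathway, rose from 236 ± 5.28 to 611 ± 21.0 CPM (SD, n = 3), and the enzymes CYP51A1 and SQLE rose by 1.47 and 0.86 on the log2 scale (SE 0.09 and 0.08), where CYP51A1 shares exons with another gene. The list was called by camera with a preset correlation (adjusted p = 2.5e-06), and the adjusted p was 0.319 with an estimated correlation.

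Primary granule and promyelocyte genes, which encode the proteases stored in early granulocyte precursors, were called higher by camera (adjusted p = 1.2e-05, and adjusted p = 0.739 with an estimated correlation). Of 19 measured members, 9 rose and 3 fell (9 and 4 adjusted over the list alone). The protease inhibitor gene CST7 rose from 205 ± 21.1 to 1253 ± 96.7 CPM, the protease PRTN3 from 121 ± 17.0 to 640.5 ± 53.8 CPM and neutrophil elastase, ELANE, from 112 ± 16.7 to 422 ± 51.0 CPM (SD, n = 3). Of the 24 measured granulocyte maturation genes, 4 rose and 9 fell (5 and 11 adjusted over the list alone; camera adjusted p = 0.228). The integrin ITGAX rose by 2.75 (SE 0.12) and CHI3L1 by 0.95 (SE 0.07), while the formyl peptide receptor FPR2 fell by 1.39 on the log2 scale (SE 0.09).

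MHC class II genes, which present antigen, were also called higher (camera adjusted p = 0.00385, and adjusted p = 0.739 with an estimated correlation). Of 11 measured members, 7 rose and none fell (7 adjusted over the list alone). HLA-DRB1 rose from 2.26 ± 0.127 to 14.7 ± 1.98 CPM and the class II regulator CIITA from 4.94 ± 0.66 to 22.1 ± 3.86 CPM (SD, n = 3), though CIITA shares exons with another gene. In overexpressing replicates 1, 2 and 3, HLA-DRB1 held 12.5, 15.1 and 16.4 CPM, CIITA 18.1, 25.8 and 22.3 CPM and HLA-DRA 7.05, 22.9 and 21.5 CPM. In replicate 1, 7 of the 11 members were above every control. The list's median log2 ratio of replicates 2 and 3 over replicate 1 was 1.57. With overexpressing replicate 1 alone against the controls, an alternative chosen after seeing the data, the list was not called (adjusted p = 0.176). The HLA members, unlike CD74 and CIITA, belong to a family of similar genes, so part of their counts is uncertain.

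Several B cell genes were higher in overexpressing replicates 2 and 3 than in replicate 1. Of 13 measured members of the B cell list, 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.435, and 2.3e-05 without overexpressing replicate 1), and the median log2 ratio of replicates 2 and 3 over replicate 1 was 1.54. MS4A1, the B cell surface protein CD20, held 2.59, 1.36 and 0.464 CPM in the controls and 0.91, 22.4 and 22.7 CPM in overexpressing replicates 1, 2 and 3. The signalling adaptor BLNK rose by 3.49 and the surrogate light chain gene IGLL1 fell by 1.77 on the log2 scale. Immunoglobulin genes together held 23.1, 22.7 and 11.3 CPM in the controls, 19.2 CPM in overexpressing replicate 1 and 231 and 249 CPM in replicates 2 and 3. Unlike the other levels, these sums were scaled by total counts without TMM factors. In all, 69 genes were at least 4 times higher in replicates 2 and 3 than in every other library, of which 30 passed the test between the groups. The 69 included XIST, which is in none of the gene lists and was chosen after its values were seen. XIST held 1.70, 0.617 and 0.446 CPM in the controls and 1.30, 19.1 and 18.0 CPM in overexpressing replicates 1, 2 and 3. Overlap of its exons with other genes was not checked.

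**Figure D2:**
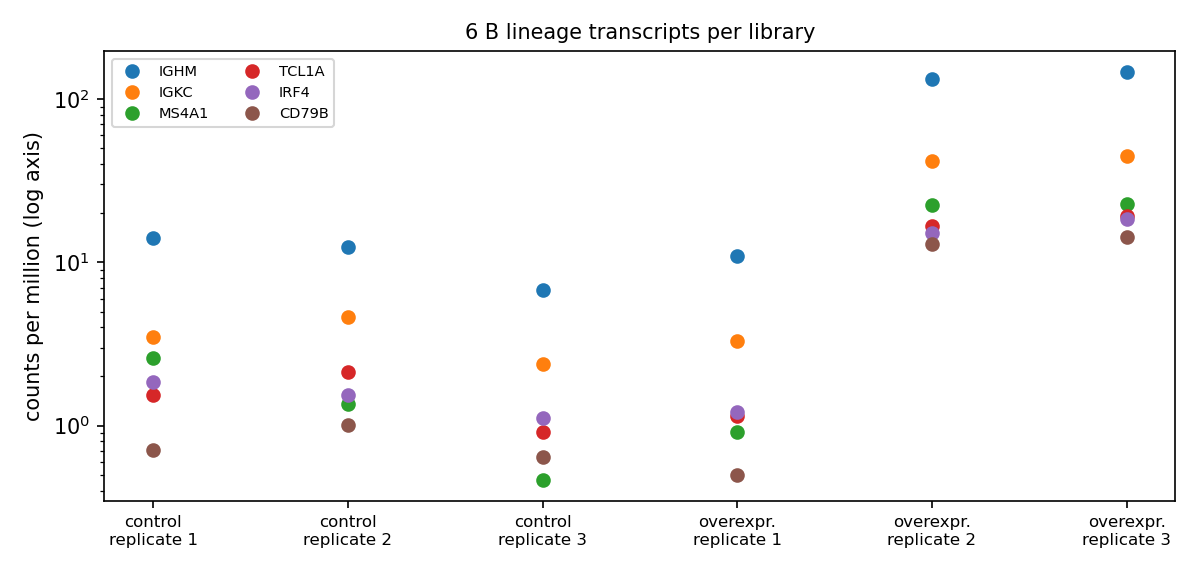
CPM, on a log axis, of 6 B lineage transcripts in each library. IGHM lies at 132 and 147 in overexpressing replicates 2 and 3 and between 6.76 and 14.2 in the other 4 libraries.

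MYC and ribosome biogenesis genes were called lower (camera adjusted p = 6.8e-06, and adjusted p = 0.739 with an estimated correlation). Of 37 measured members, 20 fell and none rose (25 fell adjusted over the list alone). The nucleolar genes NCL, NOP58 and MYBBP1A fell by 0.45, 0.45 and 0.46 on the log2 scale (SE 0.05, 0.06 and 0.07). Cytosolic ribosomal protein genes were also called lower (camera adjusted p = 0.0168, and adjusted p = 0.742 with an estimated correlation), and of 48 members 4 fell and 1 rose (1 and 1 adjusted over the list alone). RPS12 and RPL11 fell by 0.90 and 0.49 and RPL10A rose by 0.85 on the log2 scale. The call on ribosomal proteins was lost without control replicate 3 (adjusted p = 0.336), without overexpressing replicate 1 (0.144) and without overexpressing replicate 2 (0.0943), and by fry (0.347).

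**Figure D3:**
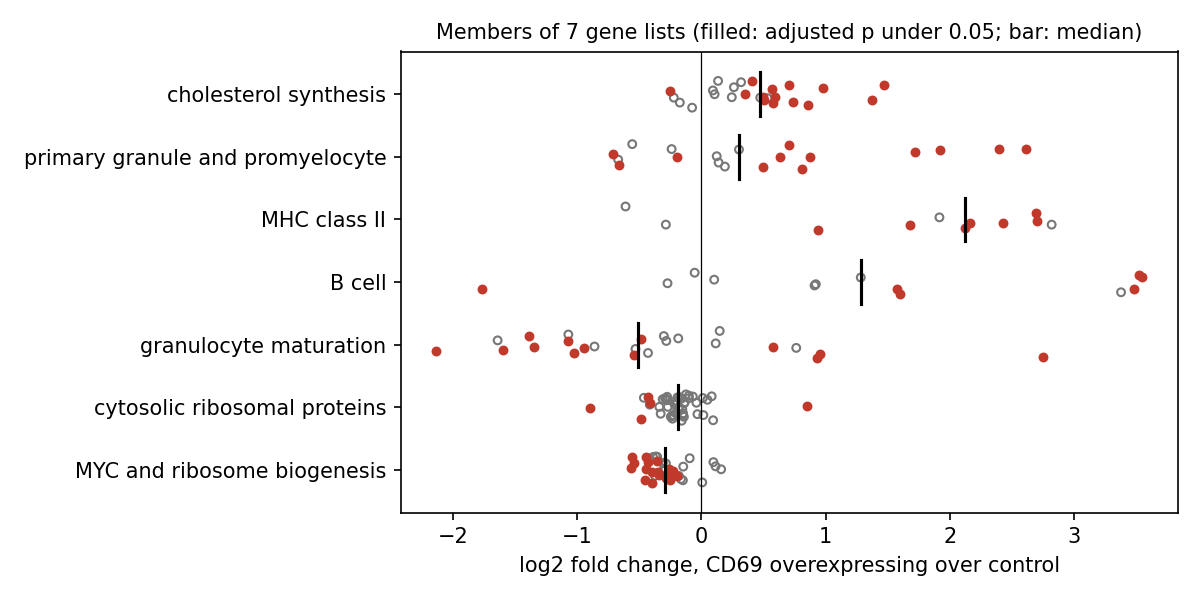
Log2 fold change of each measured member of 7 gene lists, filled where the adjusted p was under 0.05, with the list median as a bar. The median is 0.47 for cholesterol synthesis and -0.29 for MYC and ribosome biogenesis.

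The lists of growth and stress genes were not called by camera over all 6 libraries and all genes without a block. With the replicate number as a block, autophagy and lysosome was called higher and G2/M phase lower, as given below. S phase genes had 6 higher and 8 lower of 34 (7 and 16 adjusted over the list alone; adjusted p = 0.266, and 0.0161 with chromosomes 6, 15, 20 and X left out), with GINS1 up by 1.05 and CLSPN, which fell by 0.80. G2/M phase genes had 4 higher and 9 lower of 35 (5 and 11 adjusted over the list alone; adjusted p = 0.125, and 0.0133 without control replicate 3), with CDC25C up by 2.98 and TPX2, which fell by 0.64. Of 29 genes of the unfolded protein and integrated stress response, 5 rose and 9 fell (6 and 10 adjusted over the list alone; adjusted p = 0.138), among them SESN2, PSAT1 and SLC7A5, which fell by 1.04, 0.84 and 0.76. The p53 targets had 5 higher and 4 lower of 24 (7 and 4 adjusted over the list alone; adjusted p = 0.877), and the apoptosis regulators 4 higher and 6 lower of 29 (8 and 6 adjusted over the list alone; adjusted p = 0.964). Both of these had a negative median and a positive mean. The anti-apoptotic BCL2A1 rose by 1.47 and BCL2L1 fell by 0.61. Autophagy and lysosome genes had 12 higher and 7 lower of 31 (13 and 8 adjusted over the list alone; adjusted p = 0.192, and 0.0118 without control replicate 3), with the cholesterol exporter of the lysosome, NPC1, up by 1.62 and the protease CTSD, which shares exons with another gene, up by 1.53. Glycolysis and hypoxia genes had 9 higher and 6 lower of 34 (11 and 6 adjusted over the list alone; adjusted p = 0.340), with ALDOC up by 2.34. Nuclear genes of oxidative phosphorylation had 2 higher and 1 lower of 40 (0 and 0 adjusted over the list alone; adjusted p = 0.435). The 13 mitochondrially encoded genes had 3 higher (3 adjusted over the list alone; adjusted p = 0.435).

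Immune and signalling lists likewise were not called by camera without a block, while MHC class I and presentation was called higher with the replicate block. NF-kB and inflammatory genes had 8 higher and 5 lower of 27 (8 and 6 adjusted over the list alone; adjusted p = 0.192), with a negative median and a positive mean. The chemokine CCL5 rose from 24.3 ± 2.20 to 133 ± 5.71 CPM (SD, n = 3) and TNF rose by 1.86 on the log2 scale (SE 0.14). Immediate early genes had 8 higher and 5 lower of 27 (11 and 6 adjusted over the list alone; adjusted p = 0.538), with EGR1 up by 2.58 and DUSP4, which fell by 1.09. JAK-STAT targets had 7 higher and 5 lower of 24 (8 and 5 adjusted over the list alone; adjusted p = 0.968), where the median was positive and the test direction downward, with PIM1 up by 1.00 and CCND2, which fell by 1.34. Interferon response genes had 8 higher and 6 lower of 39 (10 and 6 adjusted over the list alone; adjusted p = 0.538), with SAMD9 up by 2.36 and HERC5, which fell by 0.65. MHC class I and presentation genes had 7 higher and 2 lower of 16 (8 and 3 adjusted over the list alone; adjusted p = 0.125, and 0.0183 without control replicate 3), with HLA-C, which shares exons with HLA-B, up by 1.24. Adhesion and migration receptors had 6 higher and 4 lower of 24 (7 and 5 adjusted over the list alone; adjusted p = 0.599), with the chemokine receptor CXCR4 up by 1.33 and ICAM3, which fell by 1.43. Of 20 sphingosine-1-phosphate genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone; adjusted p = 0.435), with ASAH1 up by 0.33, SPHK1, which fell by 0.79, and SPNS2, which fell by 0.60. Checkpoint and immune ligand genes had 5 higher and 5 lower of 23 (5 and 5 adjusted over the list alone; adjusted p = 0.599), with CD276 up by 2.63 and SIGLEC9, which fell by 3.33.

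Lists of differentiation and of other cell types were not called by camera without a block either. The mast cell, basophil and eosinophil list was called lower with the replicate block. Retinoic acid response genes had 4 higher and 5 lower of 21 (6 and 10 adjusted over the list alone; adjusted p = 0.667), with CD38 up by 1.52 and DHRS3, which fell by 1.42. Stem and progenitor genes had 2 higher and 5 lower of 17 (3 and 7 adjusted over the list alone; adjusted p = 0.180), with DNMT3B, which fell by 1.37, and HOXA5, which fell by 1.29. Monocyte and macrophage genes had 4 higher and 5 lower of 17 (4 and 5 adjusted over the list alone; adjusted p = 0.538), with FCN1 up by 1.11 and CCR2, which fell by 1.92. Coagulation and fibrinolysis genes had 4 higher and 3 lower of 17 (4 and 3 adjusted over the list alone; adjusted p = 0.266, and 0.0179 without overexpressing replicate 1), with PLAUR up by 0.96 and ANXA2, which fell by 0.92. T and NK cell genes had 5 higher and 2 lower of 10 (5 and 2 adjusted over the list alone; adjusted p = 0.609), with a positive median against a downward test, and NCAM1, which fell by 1.87. Mast cell, basophil and eosinophil genes had 1 higher and 3 lower of 9 (2 and 5 adjusted over the list alone; adjusted p = 0.192), with KIT, which fell by 2.25. Of 8 megakaryocyte and platelet genes 2 rose (5 adjusted over the list alone; adjusted p = 0.466), NFE2 by 0.60 and FLI1 by 0.31. Of 5 erythroid genes only TFRC changed, and fell by 0.37 (1 adjusted over the list alone; adjusted p = 0.538), and the list's median was positive against a downward test. Of 13 fibroblast and epithelial genes only EPCAM changed, and fell by 1.04 (0 adjusted over the list alone, camera adjusted p = 0.288, and 4.1e-05 without overexpressing replicate 1). The calls of FLI1 and EPCAM were each lost without control replicate 1 or 2 and without any 1 of the overexpressing libraries.

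By chromosome, the genes of X and of chromosome 20 were higher as sets. The 326 expressed coding genes of X had a median log2 fold change of 0.49, with 219 higher and 10 lower. Their median against the control mean was 0.48 in each of the 3 overexpressing libraries. The 286 expressed coding genes of chromosome 20 had a median of 0.40, with 163 higher and 27 lower. Camera was run on all tested genes of a chromosome, coding or not and at any level. For the 583 tested genes of X it gave an adjusted p of 8.6e-11, and 0.00131 with an estimated correlation. For the 511 of chromosome 20 the camera adjusted p was 7.4e-09, and 0.0124 with an estimated correlation. Parts of other chromosomes had shifted medians as well. By a rule chosen after the medians were seen, 13 runs of at least 2 successive windows of 5 Mb were found, 9 higher and 4 lower. Their medians were at least 0.25 in size and of 1 sign, which each overexpressing library shared. Windows with fewer than 8 genes were passed over, so a run can span stretches that were not measured. That on chromosome 2 from 110 to 170 Mb, for example, held 7 windows. The runs lay on chromosomes 2, 6, 7, 10, 13, 15, 16, 20 and X, and no test was made of them. The bounds on chromosomes 6, 15 and 20 given next were also chosen after the medians were seen. Between 35 and 45 Mb of chromosome 6, 73 of 83 genes rose (median 0.77), and between 70 and 160 Mb, 111 of 202 fell (median -0.40). On chromosome 15 the median was -0.49 from 40 to 45 Mb and 0.41 from 60 to 85 Mb. On chromosome 20, 58 of 77 genes rose from 0 to 20 Mb (median 0.64), while from 30 to 35 Mb the genes were mixed, with 10 higher and 16 lower of 31 (median -0.57, quartiles -0.78 and 0.39). Of the other runs, that on chromosome 2 from 110 to 170 Mb had 44 higher and 2 lower of 79 genes (medians 0.28 to 0.47), that on chromosome 7 from 70 to 105 Mb 62 higher and 3 lower of 137 (0.26 to 0.45) and that on chromosome 16 from 25 to 35 Mb 48 higher and 4 lower of 93 (0.27 to 0.46). Several genes named above lie in these windows: PIM1 and RPL10A in the raised part of chromosome 6 and EEF1A1 and RPS12 in its lowered part. TPX2, BCL2L1 and DNMT3B lie in the mixed part of chromosome 20. Raised runs hold CXCR4 on chromosome 2, CYP51A1 and SAMD9 on 7, and BCL2A1 and CD276 on 15. They also hold ITGAD and ITGAX on 16 and CST7 on 20, and BEX1 lies on X. ANXA2 on 15 and PELATON on 20 fell within raised runs, and FLT1 lies in the lowered run on 13. Chromosomes 6, 15, 20 and X held 23.4% of the changed genes and 14.1% of the genes tested.

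**Figure D4:**
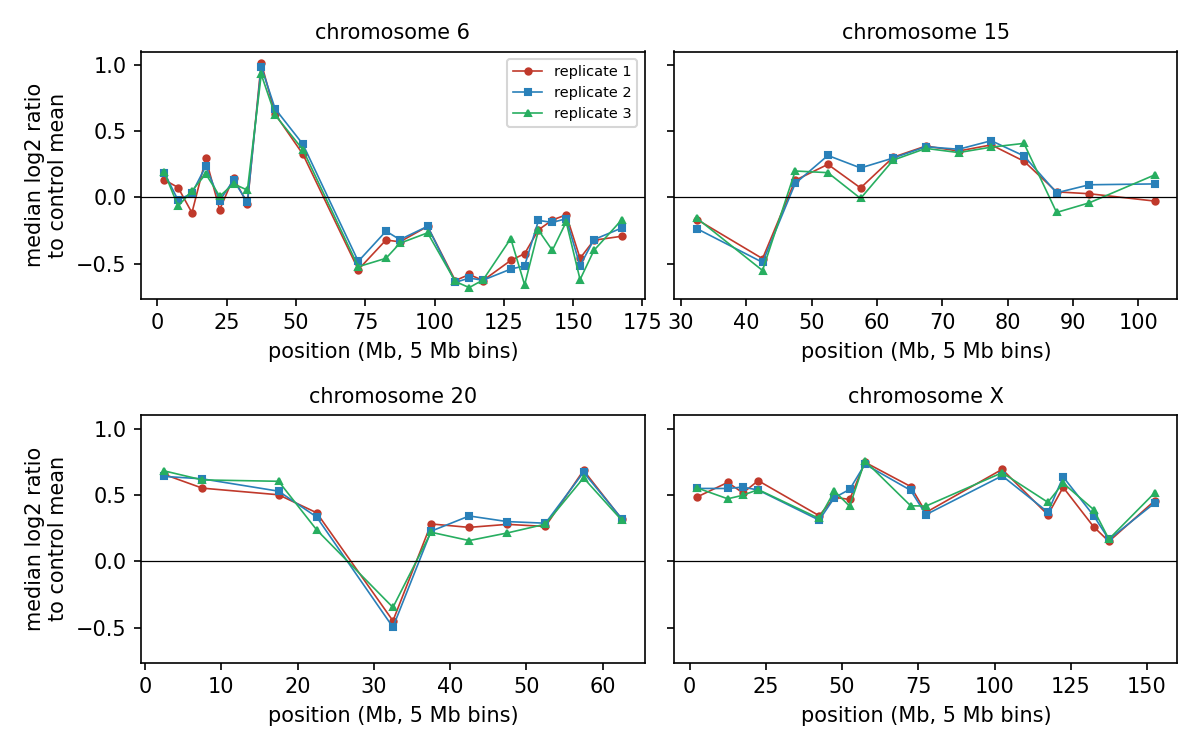
Median log2 ratio of each overexpressing library to the control mean in windows of 5 Mb along chromosomes 6, 15, 20 and X. The 3 libraries follow each other along all 4 chromosomes, and X as a whole lies at a median of 0.48 in each.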

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

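Counts divided by 4, overexpressing replicate 1 alone and the omission of chromosomes 6, 15, 20 and X were chosen after seeing the data. Against a fold of 1.2, 1723 genes were higher and 874 lower, and CD69 kept its log2 fold change of 0.33 without passing the threshold, since that test asks for more. Leaving out 1 library at a time gave 1783 to 2917 higher and 1137 to 2226 lower genes, 300 to 805 lower genes of at least 2-fold, 3 to 5 lists higher and 1 to 3 lower, and a CD69 log2 fold change of 0.27 to 0.36, with its call lost without overexpressing replicate 2. With overexpressing replicate 1 alone against the controls, a single library assumed to vary like the others, 797 genes were higher and 380 lower, 532 and 232 of them at least 2-fold, and CD69 was at 0.34 without passing. Fewer libraries lower the power of a fit, but power does not account for the fits that called more genes. Without control replicate 3, 2917 genes were higher and 2226 lower, against 2767 and 1937 with all 6 libraries. No cause was tested. Of the 18 alternatives, 15 kept the CD69 call.

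With an estimated correlation camera called 0 lists higher and 0 lower, against 3 and 2 with the preset one. Fry, which asks only whether a set moves one way, called 11 lists higher, 9 lower and 8 chromosomes. The calls of X and 20 held in each alternative run on chromosomes. No list that turned direction was called with all libraries or under the setting that turned it: JAK-STAT targets (adjusted p = 0.839 without control replicate 3, 0.968 without overexpressing replicate 1, 0.994 without overexpressing replicate 2, 0.326 by fry), oxidative phosphorylation (0.839 without control replicate 3, range 0.109 to 0.839 with 1 library left out), p53 targets (range 0.452 to 0.918 with 1 library left out, 0.452 without overexpressing replicate 1, 0.849 without the 4 chromosomes, 0.791 by fry), apoptosis regulators (0.932 without control replicate 1, 0.372 without overexpressing replicate 1, 0.849 without the 4 chromosomes, 0.520 by fry), checkpoint and immune ligands (0.478 without the 4 chromosomes) and the B cell list (0.338 with overexpressing replicate 1 alone). The cause was not tested. Of 116 named genes other than CD69, none reversed, and 12 lost their call against a fold of 1.2 and 8 with no filter. Leaving out 1 library at a time lost the call of 3 to 9 of them, among them GAPDH, FLI1 and EPCAM.

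Pairing by replicate number stays open. Deviations of same-numbered libraries from their group means correlated at -0.03, 0.05 and 0.07, but RPS12 and EEF1A1 peaked in replicate 3 of both groups. The replicate block gave 3194 higher and 2669 lower genes, 5 lists higher and 4 lower. The lists added were autophagy and lysosome (adjusted p = 0.0378) and MHC class I (0.0171), higher, and G2/M phase (0.0477) and mast cell, basophil and eosinophil (0.0418), lower. In the simulation, 14% of genes with a log2 change of 0.5 were called, so small changes may be missed. Depth was not varied in it, so it does not show what depth contributes. It also held a smaller share of changed genes than were called in the data, so the share called there may differ. Splits of the 6 libraries are too few (10) for a share under 0.05. The real split gave 4704 genes and the highest other 1, the real split 5 lists and the highest other 7 (4 splits gave as many), and the real split 2 chromosomes and the highest other 5 (7 splits gave as many). In the gene count, 1 split, the real one, gave as many.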

Other observations

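The tests of RNA from another cell type and of copy number on chromosome X, of CD69 overexpression and depth for the B lineage transcripts, and of the neighbourhood of CD69 and of a swapped library were chosen only after the results were seen.

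Chromosome X and runs of windows on chromosomes 2, 6, 7, 10, 13, 15, 16 and 20 had shifted medians. The rule for runs required all 3 overexpressing libraries to share the sign, so their agreement in the runs is no separate result. On X as a whole the median was 0.48 in each library, all set against the same control mean. The tests were made on X, with the correction for GC content and length also on 20. After splines of GC content and transcript length were removed, with values for 100% of the genes, the median of X was 0.43 against 0.49 before and that of 20 was 0.37 against 0.40, which argues against such a bias as the whole cause. The median of X in overexpressing replicate 1, which lacked the B lineage transcripts, was 0.48, which argues against RNA from another cell type in replicates 2 and 3. A difference in copy number between the 2 cell populations is a candidate explanation and stays open: 89.6% of the X genes lay above the median of all expressed genes, but X was picked for its shift, so that test could only have excluded it. No DNA was analysed here, and CD69 overexpression itself cannot be told apart from a difference between the populations that each group came from.

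B lineage transcripts were high in overexpressing replicates 2 and 3. The B cell list's median log2 ratio of replicates 2 and 3 over replicate 1, 1.54, restates this and so decides nothing about CD69 overexpression. CD69 itself held 98.3, 99.1 and 95.7 CPM in replicates 1, 2 and 3, so the difference between these libraries did not follow the measured CD69 level. CD69 overexpression as a source stays open, since the contrast rests on replicate 1 alone. The counts also do not show whether the introduced sequence was counted. A deeper library is excluded, since the mean total of replicates 2 and 3 was 0.975 times that of replicate 1. RNA from B lineage cells is a candidate source that stays open: the median log2 ratio of the MHC class II genes was 1.57, between the bounds set beforehand of above 2 for this source and under 0.5 against it, 7 of these 11 genes were above every control in replicate 1, and CD74, an abundant B cell transcript, held 83.3, 113 and 109 CPM in replicates 1, 2 and 3 against 115 to 141 CPM in the controls. Of the 13 tested B cell list members, 8 reached 1 CPM in the controls and 3 were among the 69 genes, whose log2 ratio of replicate 2 over replicate 3 had an SD of 0.358. XIST, also among the 69, held 1.30, 19.1 and 18.0 CPM in replicates 1, 2 and 3, and its source was not tested.

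CD69 rose only slightly although the cells were made to overexpress it. A swapped or mislabelled library is argued against, since the lowest correlation of any library with its own group exceeded its highest with the other group by at least 0.00713. That check covers only a library placed in the wrong group. It cannot show whether whole groups were exchanged or whether the populations are those described. A change around CD69 on chromosome 12 is a candidate explanation of the rise that stays open. The median log2 fold change of the 9 coding neighbours, 0.81, lay at the 99.0th percentile of 9999 random neighbourhoods. Those held the 9 nearest coding genes at any distance and were not matched for expression, so the percentile cannot decide. The neighbours did not all move 1 way: 5 were higher and 1 lower. The expressed coding genes of the window from 5 to 10 Mb had a median of only 0.07. The neighbours had been noticed before the percentile was taken, and the counts do not show whether the introduced sequence was transcribed or counted.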
